A study of Drosophila melanogaster with 4 samples.

How the data were processed

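The series holds 4 small RNA libraries from OSC grown at 26 degrees, made from RNA of 23 to 30 nucleotides eluted from gels after purification of Flag-tagged Piwi, per the labels' protocols. The deposited values are 1 table with 2 value columns, 1 for Yb WT and 1 for Yb ΔHel-C, for 13931 gene rows and 133 transposon rows. The authors' values are in RPM (reads per 1000000 reads), as judged from the values, since the deposited header names no unit. STAR and HTSeq and the builds BDGP6 and dm6 are named in the submitters' processing notes, with no role, order or version. The rule for reads that map to several places, the strand setting and the source of the transposon sequences are not given in the sources used here. Whether the authors pooled the 2 libraries of a group or used 1 of them is not given either, so each column is reported as the authors' value of its group. The first 2 characters of the second column's name are the Δ of a Japanese text encoding, and the rest names the Hel-C group. No column of another series was present (0 columns).

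In each column 100% of the values above 0 were whole multiples of 1 step, within a tolerance of 0.01 read. The steps gave totals of 2955141 reads (Yb WT) and 2803305 reads (Yb ΔHel-C). A mean of 2 libraries with different totals would not give 1 common step. The listed rows hold 64.2% (genes) and 4.99% (transposons) of the total in Yb WT, and 78.9% and 1.81% in Yb ΔHel-C. The remaining 30.8% and 19.3% lie in no listed row, and what they hold is not given. Of all rows, 4409 were listed at 0 in both columns. All 13 mitochondrially encoded mRNA rows and 110 of the 111 histone rows were among them, and the one histone row with reads, His2B:CG33868, had 48 and 55 reads. No row was matched to the fixed lists of snoRNAs, snRNAs, tRNAs, microRNAs, ribosomal RNAs and piRNA cluster transcripts, flamenco included, and these were not analysed here.

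Before the data were examined, edgeR's quasi-likelihood test was planned for counts and limma-trend on log2 of the value + 0.5 for normalised values. Both need replicate columns and were not run, nor were the camera and fry tests of gene lists and the permutation test of shares. In their place each row is described by its ratio of RPM with an exact conditional (Clopper-Pearson) 95% interval from the recovered read counts. Folds for summaries are log2 of RPM + 0.5, which understates the change of rows with few reads. Rows with a mean of at least 1 RPM over both columns were kept, 7577 genes and 120 transposons. The planned filter asked for the minimum in at least 2 samples, which with 1 column per group was taken as 1 RPM in both columns. In that form it removes rows near 0 in 1 column, whichever way they moved, and is given as an alternative. It kept 6961 genes, of which 2892 were called 2-fold higher and 162 lower. An exact conditional binomial test on the reads, with Benjamini-Hochberg adjustment over genes or over transposons, compares the 2 columns only. The plan set no minimum fold and held a 2-fold minimum as an alternative. The 2-fold minimum was made the threshold after the data were seen, because the test covers counting error alone. With no minimum fold the test called 4327 genes higher and 583 lower, and 99 transposons lower. In simulated columns of 7577 genes for Yb ΔHel-C against Yb WT, 200 genes with a mean of at least 10 RPM were changed. The test with no minimum fold called 48.5% of the genes changed 1.5-fold, 87.3% of those changed 2-fold, 100% of those changed 4-fold and 0.149% of unchanged genes. No change was simulated in genes below a mean of 10 RPM, so the shares of changed genes called do not cover them. The intervals held the true ratio in 95.9% of genes. These simulations hold no variation between libraries, which the deposited values cannot show.

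Gene lists were fixed at the same time as the plan, apart from those named as chosen later. A list's median is set beside the medians of 10000 random lists of the same size drawn from the tested rows, matched on mean RPM in 10 classes for genes and 3 for transposons. These percentiles describe these 2 columns. Transposon names were matched to the lists by hand after the names were seen, and transposon classes were assigned by hand. The genes named in the text followed a rule fixed in advance. It takes, among genes at a mean of at least 10 RPM that pass the test, the 10 highest and 10 lowest folds and the 5 most abundant in each direction. It adds fs(1)Yb, piwi, tj, brat and up to 3 members of each list with the smallest p. 1 result that the rule gave is not reported here. The exact test on reads stood in for the planned test, and the condition on replicates was dropped. The same rule, without being planned, gave the 5 most abundant transposons, the 3 lowest and those called higher. Further list members (papi, SoYb, aub, vas, osk, RpS21, IDEFIX, HMSBEAGLE and HETA) were chosen after their values were seen.

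Positions are those of the RefSeq annotation of Release 6 (dm6), 1-based, whole gene spans, matched by symbol or unique synonym for 13873 of 13931 gene rows (99.6%). The 5 rows named by a 5-digit number were not matched by symbol or unique synonym and carry no name here. What the numbers stand for was not examined. The annotation used gives no strand, exons or UTRs. The alternatives were other scalings (TMM and RLE factors from edgeR 4.0.16 on the recovered reads, the listed reads, the gene reads, the total without the 3 genes over 1% of a column, the total without fs(1)Yb and piwi), pseudocounts of 0.1 and 1, other filters, and the threshold with no minimum fold or no test. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and R 4.3.3 were used. Where the labels call samples replicates, nothing in them says whether these came from separate cultures.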

Results

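Small RNAs bound to Flag-tagged Piwi were measured in ovarian somatic cells (OSC), a Drosophila melanogaster line derived from the somatic cells of the ovary. Piwi is the nuclear Argonaute protein that carries Piwi-interacting RNAs (piRNAs) and silences transposons. Endogenous Yb was targeted with an siRNA in all 4 libraries. Yb is the Tudor-domain protein that gathers piRNA precursors in cytoplasmic Yb bodies. The cells received a plasmid for wild-type Yb (Yb WT, 2 libraries) or for Yb lacking the domain named Hel-C (Yb ΔHel-C, 2 libraries). The comparison asks how the RNAs loaded on Piwi differ when Yb lacks Hel-C, in a study of Yb body assembly and transposon silencing.

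The deposited values give 1 column per group, in RPM (reads per 1000000 reads), for 13931 genes and 133 transposons. The replicates therefore could not be compared, and no difference below has a replicate check. The values of each column are whole multiples of the value of 1 read, 0.338 RPM for Yb WT and 0.357 RPM for Yb ΔHel-C. These steps correspond to totals of 2955141 and 2803305 reads, of which 2044044 (69.2%) and 2262288 (80.7%) lie in the listed rows. Where reads of a row were counted, a 0 allows a level of up to 1.02 RPM in Yb WT and 1.07 RPM in Yb ΔHel-C, but a row listed at 0 can also be one whose reads were not counted. Intervals below are exact 95% intervals for counting error only. The labels name no molecular identifiers, so reads are not taken as independent molecules. A row is called 2-fold higher or lower when its log2 fold on RPM + 0.5 is at least 1 in size and the exact test on its reads passes a Benjamini-Hochberg adjusted p of 0.05. That test compares these 2 columns and not the conditions.

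Transposon reads were lower in Yb ΔHel-C. All transposon rows together held 49924 RPM in Yb WT and 18068 RPM in Yb ΔHel-C, a 2.76-fold lower level (interval 2.74 to 2.79). Of the 120 transposons with a mean of at least 1 RPM, 74 were called 2-fold lower, 3 were called 2-fold higher and 43 were neither, while 111 were called lower with edgeR's TMM scaling factors and 113 with its RLE factors. The median log2 fold was -1.22, with an interquartile range of -1.70 to -0.81, and 116 of the 120 values lay below 0. Of the 62 LTR retrotransposons 44 were called lower and 18 neither, with a median log2 fold of -1.30 at the 32.1st percentile of 10000 random lists of transposons matched on mean RPM. Of the 34 LINE retrotransposons 20 were called lower, 2 higher and 12 neither, with a median of -1.23 at the 34.9th percentile. Of the 19 DNA transposons 8 were called lower, 1 higher and 10 neither, with a median of -0.90 at the 97.1st percentile. Adjusted over the list alone, the counts were the same for LTR and LINE elements, and 7 DNA transposons were lower.

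The transposons with the most reads were LTR elements. QUASIMODO had 8239 RPM in Yb WT and 2966 RPM in Yb ΔHel-C, 2.78-fold lower (2.71 to 2.85). GTWIN was 3.21-fold lower (3.11 to 3.30), ZAM 2.76-fold lower (2.67 to 2.86), Gypsy5 2.52-fold lower (2.45 to 2.59) and STALKER4 2.04-fold lower (1.97 to 2.12). Gypsy, the family after which the group is named, went from 3014 to 667 RPM, 4.52-fold lower (4.30 to 4.75). Among rows with a mean of at least 10 RPM the LINE element HELENA_RT showed the lowest ratio, from 1069 to 131 RPM, 8.14-fold lower (7.31 to 9.09). G was 6.09-fold lower (3.29 to 12.3) and DMRT1B 5.02-fold lower (3.71 to 6.91). The 3 rows called 2-fold higher, none of which was called with TMM or RLE scaling, were TART-A, a telomeric retrotransposon (2.16-fold, 1.69 to 2.79), S2 (2.11-fold, 1.28 to 3.56) and G2, which had 2 reads in Yb WT and 10 in Yb ΔHel-C. The second TART row, TART_B1, was 1.61-fold lower (1.48 to 1.75), past 2-fold with TMM and RLE, and the telomeric HETA had 38 reads in each column.

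Of the 18 families on the list of gypsy-group elements active in the ovarian soma, 14 were called 2-fold lower, none higher and 4 neither, with the same counts when adjusted over the list alone. The values of IDEFIX (1.71-fold lower, 1.62 to 1.81) and HMSBEAGLE (1.24-fold lower, 0.852 to 1.82) did not reach 2-fold on the authors' totals, and both passed it with TMM (log2 folds -1.62 and -1.13) and RLE (-1.67 and -1.17). The list's median log2 fold of -1.25 lay at the 56.6th percentile of such random lists. Of the 13 measured families on the list of other transposons, 3 were called lower, 1 higher and 9 neither, also when adjusted over the list alone. Their median of -0.85 lay at the 95.01st percentile.

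**Figure D1:**
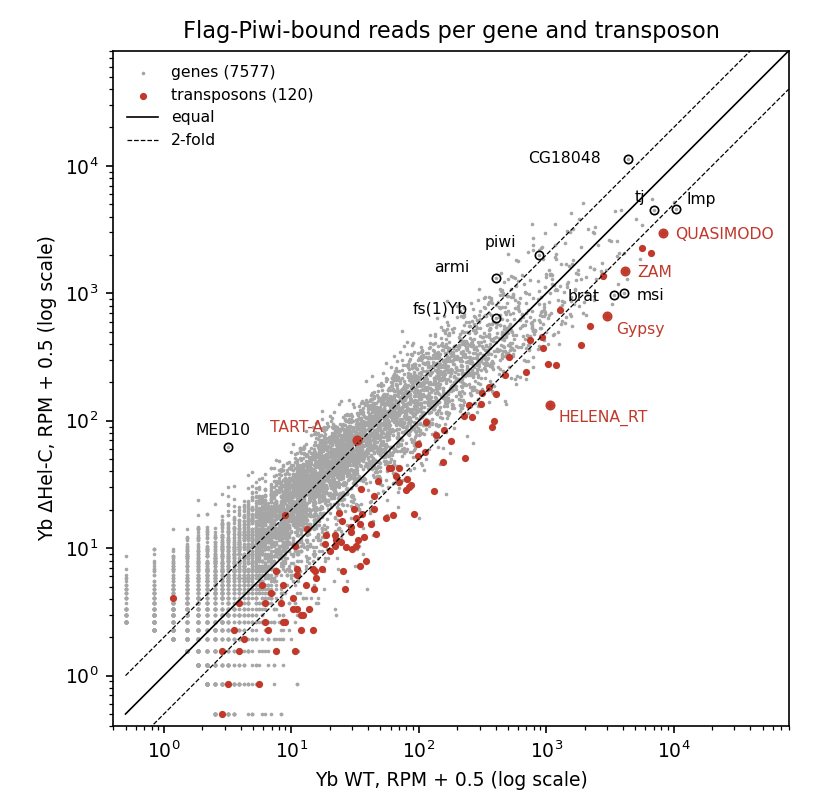
RPM plus 0.5 in Yb WT (x axis) and Yb ΔHel-C (y axis), both on log scales, for the 7577 genes (grey points) and 120 transposons (red points) with a mean of at least 1 RPM; each point is 1 row of the deposited values, the solid line marks equal values and the dashed lines 2-fold differences. Of the transposons, 116 lie below the line of equality, while 6139 genes lie above it and 1438 below it on the authors' totals, a split that depends on the scaling.

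Gene reads together were 788939 RPM in Yb ΔHel-C against 641767 RPM in Yb WT, 1.23-fold higher on the authors' totals (interval 1.227 to 1.232), a direction that turned when TMM (0.685-fold) or RLE (0.662-fold) scaling factors were used. Of the 7577 genes with a mean of at least 1 RPM, 3075 were called 2-fold higher, 243 were called 2-fold lower and 4259 were neither. The median log2 fold was 0.89, with an interquartile range of 0.24 to 1.44. The median log2 fold was 0.78 over the 3025 genes with a mean from 1 to 10 RPM, 1.09 over the 3209 genes from 10 to 100 RPM, 0.57 over the 1224 genes from 100 to 1000 RPM and -0.20 over the 119 genes at 1000 RPM or more. In that last class 21 genes were called 2-fold higher and 20 were called 2-fold lower on the authors' totals, against 2 and 61 with TMM and 2 and 63 with RLE. Across genes, which are not independent replicates, Spearman's correlation of log2 fold with mean RPM was 0.00348 over all 7577 genes and -0.291 over the 4552 genes with a mean of at least 10 RPM. Gene reads were also spread more evenly. The 10 genes with the most reads held 9.87% of the gene reads in Yb WT and 6.73% in Yb ΔHel-C, and 50% of the gene reads lay in 200 genes and 359 genes. After both columns were thinned to 1896511 gene reads, these numbers were 200 and 358.

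Of the genes called on the authors' totals, 92.7% were higher, and this split depended on the scaling. TMM and RLE take most rows as unchanged, and nearly all rows are genes. They therefore bring the median log2 fold of genes near 0 (0.10 with TMM, 0.054 with RLE) whichever way genes moved as a whole. Neither these factors nor the authors' totals can decide that direction. With TMM factors the median log2 fold of genes moved by -0.79, and 651 genes were called higher and 867 lower, a split of 42.9%. With RLE factors it moved by -0.84, and 547 genes were called higher and 920 lower, a split of 37.3%. Scaling to the gene reads alone moved it by -0.28, with 2078 higher and 381 lower. Of the 38 genes named here or by the same rule that were 2-fold higher on the authors' totals, 22 fell under 2-fold with TMM and 24 with RLE.

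Reads on the 2 genes whose proteins were put into or purified from the cells were examined first. The reads on fs(1)Yb, the gene of Yb (X chromosome, 2720468 to 2724158, dm6), were 406 RPM in Yb WT and 645 RPM in Yb ΔHel-C, 1.59-fold higher (1.48 to 1.71), a direction that turned with TMM (log2 fold -0.18) and RLE (-0.23). Those on piwi (2L, 10982205 to 10987420) were 873 and 1998 RPM, 2.29-fold higher (2.19 to 2.40), which was no longer 2-fold with TMM (log2 fold 0.35) and RLE (0.30). Reads from plasmid and endogenous RNA cannot be separated in these values, so neither gene checks the siRNA or the plasmid.

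Of the 119 genes with a mean of at least 1000 RPM, 65 had a lower value in Yb ΔHel-C. Imp, an RNA-binding protein gene (X, 10787869 to 10824277), went from 10480 to 4617 RPM, 2.27-fold lower (2.22 to 2.32). The microtubule-linked gene jvl (3R, 14741582 to 14795868) went from 10062 to 5176 RPM, 1.94-fold lower (1.91 to 1.98). The transcription factor gene traffic jam, tj (2L, 19464267 to 19467758), whose 3' UTR is a known source of piRNAs in these cells, went from 6972 to 4481 RPM, 1.56-fold lower (1.52 to 1.59). The translational repressor gene brat (2L, 19133816 to 19179758), another known source, went from 3384 to 972 RPM, 3.48-fold lower (3.33 to 3.63). The list of genes whose 3' UTR is a known source held tj and brat, of which brat was called 2-fold lower and tj was not, also when adjusted over the list alone. Fs(2)Ket, which encodes importin beta, was 1.67-fold lower (1.63 to 1.71) and CrebA 1.23-fold lower (1.21 to 1.26). With TMM the log2 folds of jvl, tj, Fs(2)Ket and CrebA were -1.80, -1.48, -1.58 and -1.14, past 2-fold, and with RLE they were lower still.

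Other abundant genes were higher. CG18048 (3R, 6346111 to 6347519), the row with the most reads in Yb ΔHel-C, went from 4401 to 11286 RPM, 2.56-fold higher (2.51 to 2.62). The cytochrome P450 gene Cyp4p1 (2R, 9240041 to 9242139) was 2.60-fold higher (2.52 to 2.68), and the zinc finger gene bowl (2L, 3771700 to 3784121) was 2.73-fold higher (2.64 to 2.82). With TMM the log2 folds of CG18048, Cyp4p1 and bowl were 0.52, 0.53 and 0.60, under 2-fold. CtBP was 1.17-fold higher (1.14 to 1.20) and Snap24 1.29-fold higher (1.25 to 1.32), directions that both turned with TMM and RLE, and for CtBP also when scaled to the gene reads.

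Among genes with a mean of at least 10 RPM, the 10 highest ratios belonged to genes with few reads in Yb WT. MED10, a Mediator subunit (3L, 16232084 to 16232777), had 8 reads in Yb WT and 172 in Yb ΔHel-C, a 22.7-fold higher level (11.2 to 53.3). CG6763 was 17.4-fold higher (6.48 to 65.7), and Cdc16, a subunit of the anaphase-promoting complex whose locus overlaps it, was 10.7-fold higher (4.65 to 30.3). Sin1, a subunit of TORC2, was 10.9-fold higher (5.30 to 26.2). The others were CG12822, CG8004, CG3156, CG1233, CG32278 and the glutamate receptor gene GluRIIB, from 8.04-fold to 10.99-fold higher.

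Among the 10 lowest ratios, CG1722 was 9.01-fold lower (4.96 to 18.0), CG34450 8.81-fold lower (4.04 to 22.8) and CG4631 7.47-fold lower (3.57 to 18.1). CG11635 was 6.24-fold lower (4.87 to 8.09) and CG8701 5.91-fold lower (4.33 to 8.23), and the loci of both overlap pdm3. The Musashi gene msi (3R, 25516118 to 25608423) went from 4111 to 997 RPM, 4.12-fold lower (3.96 to 4.30). The TCF gene pan was 5.42-fold lower (3.05 to 10.4) and PlexB 4.02-fold lower (3.42 to 4.74). CG9380 was 4.59-fold lower (2.78 to 7.97), and GstD5, whose reads can be shared with the other GstD genes, was 4.23-fold lower (2.70 to 6.89). The locus of 6 of the 10 highest and 8 of the 10 lowest genes overlaps another gene, against 50.3% of the 4529 genes with a position and this mean. The strand setting of the authors' counting is not given in the sources used here, so reads of overlapping genes are uncertain.

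Of 14 piRNA biogenesis genes, 9 were called 2-fold higher, 1 lower and 4 neither, and adjusted over the list alone 9 were higher and 2 lower. The helicase gene armi went from 405 to 1310 RPM, 3.24-fold higher (3.03 to 3.46), Hsp83 was 2.40-fold higher (2.23 to 2.60) and papi 4.95-fold higher (3.44 to 7.30). Of the genes called higher, only papi stayed past 2-fold with TMM (log2 fold 1.44) and RLE (1.39). With the same factors armi was at 0.85 and 0.80, and Hsp83 at 0.42 and 0.37. SoYb, a relative of Yb, was 2.02-fold lower (1.87 to 2.17). The list's median of 1.15 lay at the 88.7th percentile of matched random gene lists, inside their 95% range of 0.27 to 1.32, and was 0.32 with TMM and 0.27 with RLE. Of 14 genes for silencing by Piwi in the nucleus, 10 were called higher and 4 neither, also when adjusted over the list alone, with a median of 1.39 at the 98.3rd percentile (0.56 with TMM and 0.51 with RLE). Mi-2 was 3.57-fold higher (3.05 to 4.19) and CoRest 2.88-fold higher (2.54 to 3.26). Both fell under 2-fold with TMM (log2 folds 0.987 and 0.68) and RLE (0.94 and 0.63). Of the genes called higher, only HDAC1 (56 and 254 reads) and arx stayed past 2-fold with these factors. The value of arx rests on 3 reads in Yb WT and 16 in Yb ΔHel-C (5.62-fold higher, 1.61 to 30.1). Su(var)2-10, a SUMO ligase gene and the most abundant on the list, was 1.83-fold lower (1.78 to 1.90), past 2-fold with TMM and RLE.

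Markers of the cell types of the ovary were set beside these genes. Of 20 measured genes of somatic follicle cells, 4 were called higher, none lower and 16 neither, also when adjusted over the list alone, with a median of 0.45 at the 18.4th percentile, which turned negative with TMM (-0.367) and RLE (-0.415). The receptor genes Egfr (3.62-fold higher, 3.26 to 4.03) and ptc (2.96-fold higher, 2.82 to 3.11) were among those called. Of 13 measured germline genes, none was called higher, 2 were called lower and 11 were neither, also when adjusted over the list alone, with a median of 0.30 at the 6.60th percentile, which turned negative with TMM (-0.468) and RLE (-0.517). The called genes were orb (3.54-fold lower, 2.41 to 5.34) and aub (2.17-fold lower, 1.12 to 4.40). The highest germline genes were tud (681 and 568 RPM) and spn-E (219.6 and 398 RPM, close to no change with RLE at a log2 fold of -0.036), while vas had 0 and 2 reads and osk 1 read in each column.

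**Figure D2:**
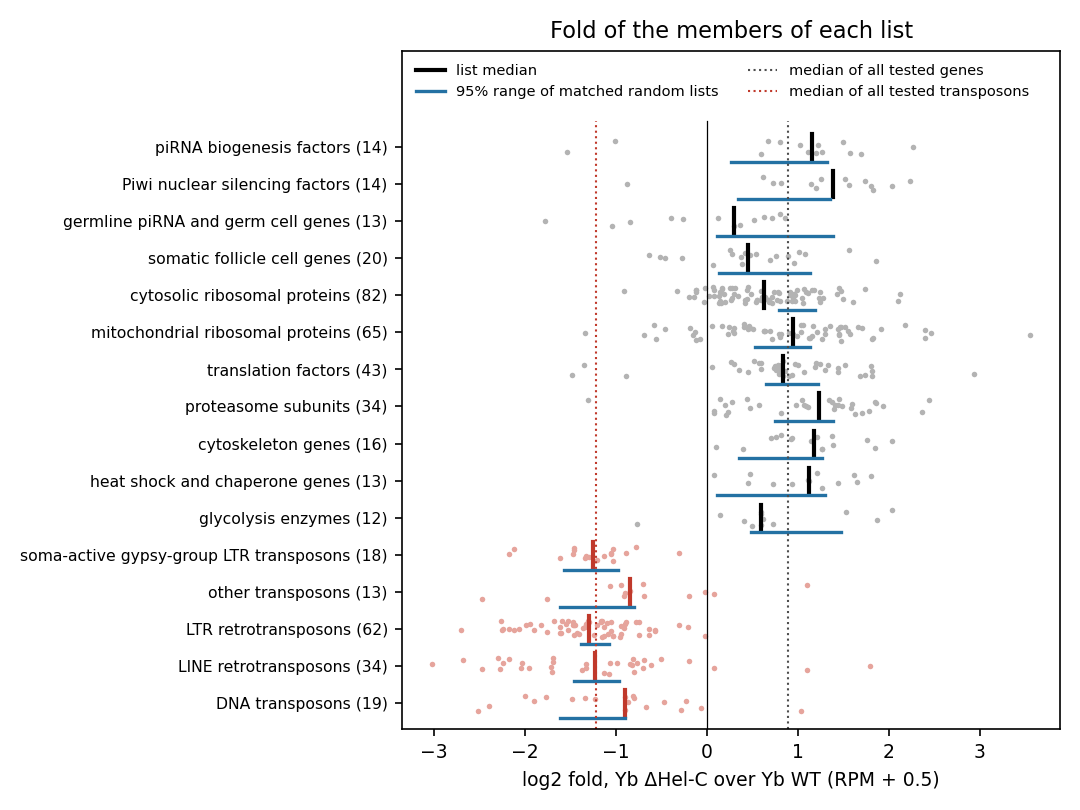
Log2 fold on RPM + 0.5, Yb ΔHel-C over Yb WT (x axis), for the measured members of each list (points, with their number in parentheses), the list's median (vertical bars) and the 95% range of the medians of 10000 random lists matched on mean RPM (blue lines). The cytosolic ribosomal proteins, at a median of 0.62 that turns negative with TMM and RLE, lie below the range of their random lists, 0.79 to 1.19, and the transposon lists lie at negative values.

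Of 82 cytosolic ribosomal protein genes, 18 were called higher, none lower and 64 neither, with a median of 0.62 at the 0.02nd percentile of matched lists, which turned negative with TMM (-0.201) and RLE (-0.250). RpL3 (2.36-fold, 2.21 to 2.52) and RpL15 (3.36-fold, 2.76 to 4.13) were called higher, whereas RpS21 had 350 and 344 RPM. The loci of RpL3 and RpL15 overlap snoRNA genes, so the origin of their reads is uncertain. Loci of other examples overlap genes too, such as that of mRpS9 with ArgRS-m. Of 65 mitochondrial ribosomal protein genes 25 were called higher and 40 neither (24 higher when adjusted over the list alone), with a median of 0.94 at the 73.8th percentile (0.17 with TMM, 0.14 with RLE) and examples in mRpS16 (4.85-fold, 2.75 to 9.13), mRpS9 (3.62-fold, 2.43 to 5.55) and mRpS30 (2.86-fold, 1.87 to 4.46). Of 43 translation factors 15 were called higher, 1 lower and 27 neither, with a median of 0.83 at the 22.45th percentile, which turned negative with TMM (-0.0095) and RLE (-0.059). eIF4A was 3.35-fold higher (2.97 to 3.78) and eEF2 2.27-fold higher (2.10 to 2.46), and the cap-binding repressor gene eIF4EHP, at 1961 and 701 RPM, was 2.80-fold lower (2.66 to 2.95). Of 34 proteasome genes 20 were called higher and 14 neither, with a median of 1.23 at the 82.3rd percentile (0.47 with TMM, 0.43 with RLE). Rpn6 was 5.34-fold higher (3.59 to 8.19), Rpn3 3.58-fold higher (2.33 to 5.66) and Rpn2 2.71-fold higher (1.96 to 3.79).

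Of 16 cytoskeleton genes 9 were called higher and 7 neither, with a median of 1.17 at the 93.2nd percentile (0.33 with TMM, 0.28 with RLE). The tubulin genes betaTub56D (2.41-fold, 2.21 to 2.63) and alphaTub84B (2.60-fold, 2.24 to 3.01) were higher. Act5C was at 1.76-fold (1.65 to 1.87), which came close to no change with TMM (log2 fold -0.031) and RLE (-0.081). Reads of tubulin and actin genes can be shared with near-identical copies. Of 13 heat shock and chaperone genes 7 were called higher and 6 neither, with a median of 1.12 at the 89.6th percentile (0.35 with TMM, 0.30 with RLE). The heat shock factor gene Hsf went from 788 to 2412 RPM, 3.06-fold higher (2.92 to 3.21), and Hsc70-3 was 3.13-fold higher (2.86 to 3.43). Of 12 glycolysis genes 3 were called higher and 9 neither, with a median of 0.59 at the 5.53rd percentile, which turned negative with TMM (-0.232) and RLE (-0.281). The 3 were Eno (2.90-fold, 2.41 to 3.51), Pgi (3.70-fold, 2.87 to 4.81) and Gapdh2 (4.31-fold, 2.68 to 7.22). For the cytosolic ribosomal, translation, proteasome, cytoskeleton, heat shock and glycolysis lists the counts adjusted over the list alone were the same.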

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

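The tests of a single scaling factor, of counting error in picking genes and of ribosomal protein reads were chosen after the result was seen, and the test of columns per group before. Of 5 gene rows named only by a 5-digit number, 3 had more reads in Yb ΔHel-C than in Yb WT beyond counting error, and no comparison above names them. The row 41973 had 537 RPM against 304 RPM, the row 41882 had 293 against 164 RPM, and the row 41883 had 15.7 against 4.40 RPM. TMM and RLE shift the log2 of every ratio of RPM, taken with no pseudocount, by -0.84 and -0.89. That brings the ratios of 41973 and 41882, 1.77 and 1.78 on the authors' totals, close to equality, with no clear direction.

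Genes with a mean of at least 1000 RPM (median log2 fold -0.20) had lower folds than genes with a mean from 10 to 100 RPM (1.09). The latter class had the highest median of the classes of mean RPM. The medians from 1 to 10 RPM (0.78) and from 100 to 1000 RPM (0.57) lay closer to that of the most abundant genes. The difference from the median of the 10 to 100 RPM class was -1.28 on the log2 scale (95% bootstrap interval over genes -1.50 to -0.91). This interval takes no account of how the class was chosen. A single scaling factor cannot make this difference, which was the observation itself. With TMM and with RLE it was -1.30, since any such factor leaves it nearly unchanged. The 100 genes with the most reads in a random part of the Yb WT reads had, in the other part, a lower median log2 fold than the other genes (difference -1.49, interval -1.64 to -1.25). For these 100 genes counting error is small beside this difference, so the test could hardly have come out otherwise and adds little. Both parts come from 1 column, so deviations of the Yb WT libraries themselves stay open. A pick on Yb WT reads alone favours lower folds. The genes at 1000 RPM or more were picked on the mean of both columns, which this test does not cover. An effect of the Hel-C deletion and a difference between 2 libraries cannot be told apart, because there is 1 column per group (1 column each for Yb WT and Yb ΔHel-C).

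Reads on genes together were higher on the authors' totals, a direction that TMM and RLE turn. RPM values of a column share 1 fixed total, so this rise mirrors falls elsewhere. Transposon rows went from 49924 RPM in Yb WT to 18068 RPM in Yb ΔHel-C. Reads in no listed row went from 308309 to 192993 RPM. The rise therefore does not by itself need added RNA from genes. One candidate explanation is fragments of abundant mRNA carried through the purification of Piwi, which would favour ribosomal protein genes. They took 1.85% of the added genic RPM (interval 1.76 to 1.93) against 0.640% of the genic RPM in Yb WT. Any list with a ratio above the 1.23 of all gene reads takes such a larger share. The ribosomal protein list, at 1.66, and the heat shock list, at 2.60, both lie above it, so the share cannot decide the question. The median log2 fold of the ribosomal protein genes, 0.62, lay below the 0.99 of matched random lists, the opposite of what this explanation needs. The explanation stays open, because mRNA levels were not used here.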

How the results depend on the processing

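No paired analysis was possible because each group has 1 column with no replicate number, and for the same reason the planned fits with DESeq2 and limma-voom, the left-out replicates and the camera tests were not run. Non-coding classes had no rows to leave out. The scalings to listed reads and to gene reads, the filter on 50 reads over both columns and the threshold with no test were added after seeing the data. The planned filter, taken as 1 RPM in both columns, and the planned threshold with no minimum fold became alternatives at that point. The ratio of all transposon reads, 0.362 on the authors' totals, was 0.310 per listed reads, 0.294 per gene reads, 0.195 with RLE and 0.202 with TMM. The median log2 fold of transposons was -1.43, -1.50, -2.04 and -1.99 in the same order, and that of genes was 0.68, 0.61, 0.054 and 0.10. The ratio of all gene reads, 1.23, was 1.05 per listed reads, 1.22 without the genes over 1%, and reversed to 0.662 with RLE and 0.685 with TMM. Genes called 2-fold higher (3075 of 7577) numbered 547 with RLE, 651 with TMM and 1114 of the 2982 tested with 50 reads in both columns. Genes called 2-fold lower (243) numbered 381 per gene reads, 920 with RLE, 867 with TMM, 583 with no minimum fold and 377 with no test. Stricter filters tested fewer genes. They gave 135 of 5577 at a mean of 5 RPM, 83 of 2982 with 50 reads in both columns and 111 of 4754 with 50 reads over both. Transposons called lower (74) numbered 113 with RLE, 111 with TMM, and 33 with 50 reads in both columns, where fewer rows were tested. The median of genes was 0.94 with a pseudocount of 0.1, 0.84 with 1, 0.78 with no filter, 0.96 at a mean of 5 RPM, 0.76 with 50 reads in both columns and 0.95 with 50 over both. Directions that reversed with RLE and TMM were those of the somatic (-0.415, -0.367), cytosolic ribosomal (-0.250, -0.201), translation (-0.059, -0.0095) and glycolysis lists (-0.28, -0.23), of the germline list (-0.517, -0.468), whose main interval held 0, and of CtBP (-0.67, -0.62, and -0.072 per gene reads), Snap24 (-0.53, -0.48), fs(1)Yb (-0.23, -0.18), Act5C (-0.081, -0.031) and, with RLE, spn-E (-0.036). The reversed values of the translation list, Act5C and spn-E lie close to 0 and show no clear direction. Relative to the median of all rows of their kind, the mitochondrial ribosomal list moved to 0.30 at a mean of 5 RPM and 0.46 with 50 reads over both columns, the germline list to -0.24 and the other transposons to 0.25 with 50 reads in both. As for depth, the read test with no minimum fold called 48.5% of simulated 1.5-fold changes and 87.3% of 2-fold changes. These changes were simulated only in genes with a mean of at least 10 RPM.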

Other observations

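The 4 gene groups of this paragraph were chosen after their members had been seen among the highest folds, so their counts, on the authors' totals alone, are descriptions and not independent evidence, while the tests of transposon families, neighbouring genes and gene span were chosen before their results were seen. Of 33 aminoacyl-tRNA synthetase genes, which load tRNAs with amino acids, 23 were called 2-fold higher and none lower, with a median log2 fold of 1.43 at the 99.4th percentile of matched random lists. ProRS-m was 6.62-fold higher and MetRS 6.47-fold higher, whereas MetRS-m had 21.0 and 11.4 RPM. Of 21 nucleoporin genes 15 were called higher and none lower, with a median of 1.41 at the 98.9th percentile, among them Nup50 (7.04-fold) and Nup358 (3.77-fold). The 22 Mediator subunits around MED10 had 10 called higher and a median of 1.003 at the 73.8th percentile. The 21 V-ATPase subunits had 10 called higher and a median of 0.98 at the 81.5th percentile.

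The 20 genes at a mean of at least 1000 RPM that were called 2-fold lower included, besides msi, brat, Imp and eIF4EHP, unk (3.99-fold lower, 3.81 to 4.17), Tis11 (2.84-fold lower, 2.68 to 3.01), AGO1, the Argonaute of the microRNA pathway (2.30-fold lower, 2.19 to 2.42), roq (2.18-fold lower, 2.06 to 2.30) and Hrb27C (2.09-fold lower, 2.00 to 2.19). Others are the TOR inhibitor gene chrb (3.30-fold lower, 3.18 to 3.42), the plexin gene PlexA (2.95-fold lower, 2.86 to 3.04) and the polarity gene l(2)gl (3.08-fold lower, 2.93 to 3.25). These genes were chosen after their values were seen, and no enrichment was tested.

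The hypothesis that transposon families active in the ovarian soma lost more reads than other families was written down before its test. By the rule set in advance it was not borne out: the median of the soma list lay at the 56.6th percentile of matched random lists, -1.25 against -1.29 for those lists. The random lists were drawn from all tested transposons, soma families included. The fixed list of other transposons had a median of -0.85, with 3 of 13 called 2-fold lower against 14 of 18 on the soma list. That contrast was not tested. The hypothesis that neighbouring genes share reads or a precursor was also written before its test. Across 6228 pairs of adjacent genes that do not overlap, Spearman's correlation of log2 fold was 0.0842, above the highest of 1000 shuffles (0.0540). That value lay under the bound of 0.1 set in advance, so by that rule the hypothesis was not borne out. The rule named no interval, and the 95% bootstrap interval of 0.0576 to 0.109 held the bound. Across 1303 overlapping pairs the correlation was 0.144, and shared counting may add to it. Gene span was tested as a length effect. Spearman's correlation of log2 fold with span was -0.166 across 7530 genes (95% bootstrap interval -0.189 to -0.145), inside the bound of 0.2 set in advance. Genes are not independent replicates in these correlations.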
